A study of Mus musculus with 6 samples.

How the data were processed

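RNA from colonic epithelial cells of 6 female C57BL/6 mice was hybridised to Affymetrix mouse expression arrays. Per the labels' protocols, washed colons were shaken in a calcium- and magnesium-free salt solution with DTT and EDTA, the released cells were passed through a strainer and enriched by centrifugation, and total RNA was extracted with Trizol and labelled as biotinylated cRNA. No cell sort is named, so other cell types of the mucosa can be present. Samples were grouped by their titles into hindlimb unloading (3 arrays, 28 days of unloading) and control (3 arrays). Mice had been assigned to the groups at random by weight, per the labels. Mouse numbers are not shared between the groups, so nothing pairs the samples. Where the titles' numbers do not mark separate animals, p-values measure only the spread between these arrays. The labels give no cage, array batch or scan date.

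The deposited value table holds intensity values, the linear brightness of each probe set, all above 0. Per the submitters' processing notes MAS5 was used; its version, its role and any further step are not given in the sources used here. The trimmed means (2% off each end) ran from 69.4 to 72.9, a spread of 5.08%, so the arrays had not been left at 1 common MAS5 target, and the scaling the authors applied stays unsettled. This spread followed the groups, with 72.3 to 72.9 in unloading and 69.4 to 71.3 in control. Array medians lay between 20.5 and 21.2, close to the pseudocount used, so log2 changes of dim genes are understated. Detection calls were not used here. No further normalization between arrays was applied in the main setting.

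Probe sets were named through the platform's annotation: 34945 had 1 gene symbol, 932 several and 9160 none listed, beside 64 control probe sets. Of the symbols, 34741 matched the GRCm38.p6 gene table by gene identifier and 204 did not and kept the annotation's name; no symbol changed. That table served for names only, so no coordinates are given. Each of 18193 genes was represented by its probe set of highest mean signal over the 6 arrays. Genes with a mean log2 value under the 40th percentile of the non-control probe sets (a signal of 14.4) were left out, which removed 5086 and left 13107.

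Values were tested as log2(signal + 16) with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with a trended prior variance, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A fold change on this scale understates the change of dim genes. Gene lists of cell types, pathways and other cell types that the preparation could hold, 41 in all, were fixed before the data were examined, as were the tests of the genes, the lists and the array quality, the naming rule and the alternatives other than the one added. Several tests of explanations and the families of gene symbols were chosen after the results were seen, and are named as such where they are given. Of the 41, 40 had enough measured members. They were tested with limma's camera at its preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. It called 13 lists, 3 higher and 10 lower. With an inter-gene correlation estimated from the data, 0 of the 40 lists were called (4 had an unadjusted p under 0.05). With 3 arrays in each group that form of the test has little power. The interferon response list, with 37 of 39 genes lower, had an unadjusted camera p of 0.0431 by it. A list that it did not call is therefore not shown to be unchanged. Fry, which tests whether a list's genes move on balance one way, called 14, and its mixed test, for change in either direction, called 34; neither compares a list with other genes. Some genes belong to 2 lists.

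Genes named in the text follow a rule. The first part takes, among genes past the threshold with no overlap between groups, the 12 largest rises and the 12 largest falls. The next part takes up to 4 passing members of each list, over all genes or over the list alone, by unadjusted p, and at most 2 members, as values, from a list with none. The last part always includes Muc2, Lgr5, Mki67, Tjp1, Ocln, Cdh1, Reg3g, Il1b, Il6, Tnf, Il10, Tlr4 and Fkbp5. The rule gave 145 tested genes, of which 123 passed. Not all of them are named in the text, and many passing genes left out lost the call in at least 1 alternative.

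Alternatives were pseudocounts of 1 and 64, no filter and a filter at the 60th percentile, quantile normalization, median centring, cyclic loess, untrended and robust variance models, array weights, the mean of a gene's probe sets, leaving out probe sets of less specific design, 1 test per probe set, a threshold of 0.1, and leaving out each array in turn. Scaling each array on its bacterial hybridization controls, which are added in equal amounts to each hybridization, was chosen after seeing the data.

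The fit was tested on simulated data with the spread that limma fitted to these arrays and 13107 genes, in 10 runs. It recovered 96.4% of genes changed by a log2 of 0.5, 99.9% of those changed by 1 and 99.8% of those changed by 2, and 6.71% of its calls were false. A list shifted by 0.2 was called in 10 of 10 runs, and 0 of 390 unshifted lists were called. The simulated genes varied independently, and fewer were changed in each run than were called in these arrays. The rates for genes and lists therefore need not hold for the real arrays. Ratios of 3' to 5' control probe sets were compared by exact permutation tests. The number of arrays, 3 in each group, limits the precision.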

Results

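Gene expression was measured on Affymetrix mouse expression arrays in epithelial cells isolated from the colon of female C57BL/6 mice aged 12 weeks. C57BL/6 is a common inbred laboratory strain. The hindlimb unloading group held 3 mice (numbers 145, 146 and 148), kept unloaded for 28 days, and the control group held 3 mice (numbers 141, 143 and 144) housed in the same room. Hindlimb unloading lifts the hind legs off the cage floor and serves on the ground as a model of weightlessness. Each array is taken as 1 mouse, as the numbers in the sample titles read. The deposited table gave a linear signal for each probe set, with array medians from 20.5 to 21.2. Log2 values correlated at 0.9942 to 0.9964 between arrays of the same group and at 0.9873 to 0.9903 between groups. The first principal component held 65.9% of the variance and separated the groups, with unloading arrays between -16.5 and -14.5 and control arrays between 14.5 and 16.2. The number of arrays limits the precision of each comparison.

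The comparison of unloading with control mice asks which transcripts of the colonic epithelium differed after hindlimb unloading. The deepest falls included interferon-induced genes, antigen presentation genes and lymphocyte genes. Ifi27l2a, an interferon-induced gene, fell from a mean signal of 674.6 ± 221 (SD, n = 3) to 23.6 ± 6.0, a log2 fold change of -4.08 ± 0.22 (SE). Cyp4b1, a cytochrome P450 monooxygenase, had the largest rise, from 55.8 ± 9.1 to 282 ± 70.1, a log2 fold change of 2.03 ± 0.16. Of 13107 genes tested, 1424 were higher and 793 lower in unloading (limma, Benjamini-Hochberg adjusted p under 0.05), and 4401 had an unadjusted p under 0.05. A log2 change of at least 1 was reached by 19 of the higher and 103 of the lower genes, and a change of at least 2 by 1 higher and 27 lower genes. The unloading and control values did not overlap in 5133 genes, 39.2% of those tested, where chance gives 10%. The count of changed genes was 1166 without unloading mouse 145, 1227 without mouse 146 and 1337 without mouse 148. It was 1526 without control mouse 141, 2062 without control mouse 143 and 1171 without control mouse 144, and the higher genes alone were 933 without mouse 141. The share of higher among changed genes, 64.2% in the deposited scaling, was 50.7% after quantile normalization, 53.02% after cyclic loess and 6.08% when arrays were scaled on their bacterial hybridization controls, which moved the median of all genes from 0.00 to -0.18 log2 and was chosen after seeing the data.

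**Figure D1:**
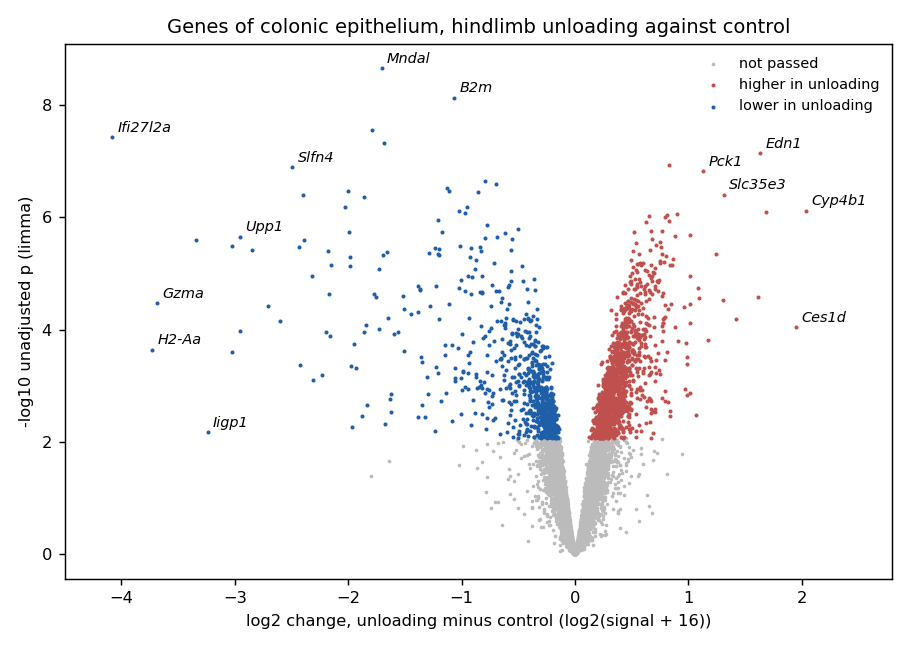
Each point is 1 of 13107 genes, with the log2 change on log2(signal + 16), unloading minus control, on the x axis and -log10 of the unadjusted limma p on the y axis. The 1424 higher genes are red and the 793 lower genes blue, and the falls reach further (Ifi27l2a at -4.08) than the rises (Cyp4b1 at 2.03).

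Changes named in the text are log2 fold changes on log2(signal + 16), unloading minus control, with the standard error of the limma fit, and signals are means ± SD of 3 arrays. Genes said to have risen or fallen kept that call in each alternative in which they were tested again, of which there were up to 20, except where an exception is given beside them. Of the 145 genes taken by the naming rule, 55 had several probe sets past the filter, and in 46 of these all pointed the same way. Emp1 alone among the named genes had another called probe set of opposite sign.

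Genes of the interferon response fell together. Of 39 measured, 37 were lower and 0 higher (38 lower when adjusted over the list alone), with a median log2 change of -1.56. With an array left out, the lower genes ran from 27, without mouse 148, to 37, without mouse 145. Ifit2 and Ifit1, which bind viral RNA and limit its translation, fell (-3.02 ± 0.28 and -2.60 ± 0.36). Usp18, a protease that dampens type I interferon signalling, fell by 2.85 ± 0.27, from a signal of 267 ± 122 to 21.7 ± 7.3. Rtp4, a receptor transporter protein induced by interferon (-2.39 ± 0.21), the nucleic acid sensor Zbp1 (-1.79 ± 0.09) and the RNA sensor Ifih1 (-0.92 ± 0.09) fell as well (limma adjusted p = 0.000689, 0.000122 and 0.000791). Iigp1, an interferon-inducible GTPase of defence against intracellular pathogens, differed by -3.24 ± 0.90 at an adjusted p of 0.043. Its signal was 535 in unloading mouse 145 against 10.6 and 45.7 in the other unloading mice and 831 to 987 in controls. The Iigp1 call was lost without mouse 146 (adjusted p = 0.106), 148 (0.124), 141 (0.106), 143 (0.0694) or 144 (0.107), as it was in 5 further alternatives, and its adjusted p ranged from 0.000496 to 0.168 over the alternatives. The members that did not pass were Gbp2 (-1.64 ± 0.58) and Mx1 (-0.12 ± 0.21). The list was called by camera with its preset correlation (adjusted p = 1.07e-26), and had an adjusted p = 0.431 with an estimated correlation. In the same arrays 15 of 16 T cell, 7 of 12 macrophage and dendritic cell and 2 of 10 B cell and plasma cell markers were lower (adjusted p = 0.442, 0.442 and 0.431 with an estimated correlation).

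MHC class II genes, which present peptides to CD4 T cells, also fell. Of 7 measured, 6 were lower and 0 higher (7 lower when adjusted over the list alone), with a median of -2.42. H2-Aa went from 1552 ± 1044 to 94.5 ± 66.1, a change of -3.73 ± 0.61 (limma adjusted p = 0.00619). Its call was lost with robust variance moderation (adjusted p = 0.0551, the highest over its alternatives, whose lowest was 2.29e-05). The beta chain gene H2-Ab1 (-2.95 ± 0.43), the invariant chain Cd74 (-2.70 ± 0.34) and Ciita, the master activator of these genes (-0.33 ± 0.05, from a signal of 20.6 ± 1.6), fell as well. The list was called lower by camera (adjusted p = 2.44e-06; adjusted p = 0.442 with an estimated correlation). Markers of other cells that present antigen were lower in the same arrays, 7 of 12 of macrophages and dendritic cells and 2 of 10 of B cells and plasma cells. Some of these markers were dim even in controls, as with Mpeg1 (a signal of 32.2 ± 0.7) and Prdm1 (26.5 ± 2.1), while Igha had 216 ± 99.0. Control mouse 141 had the lowest signal of H2-Aa among controls (500 against 2587 and 1568).

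Markers of T cells and intraepithelial lymphocytes were lower in 15 of 16 measured genes and higher in 0 (16 lower when adjusted over the list alone), with a median of -0.96. With an array left out, the lower genes ran from 10 of 17, without mouse 146 or 148, to 15 of 16, without mouse 141. The cytotoxic granule proteases Gzma and Gzmb fell (-3.69 ± 0.46 and -3.34 ± 0.30), from signals of 699 ± 485 and 427 ± 181 to 30.6 ± 7.4 and 25.0 ± 6.1. The T cell chemokine Ccl5 changed by -3.03 ± 0.50 (limma adjusted p = 0.0065, and 0.0547 with robust variance moderation, within a range of 1.73e-05 to 0.0547). Nkg7, a cytotoxic granule protein, fell by 1.75 ± 0.21, and the co-receptor Cd8a fell by 0.74 ± 0.11. The list was called lower by camera (adjusted p = 3.23e-11; adjusted p = 0.442 with an estimated correlation). Macrophage and dendritic cell markers were lower in 7 of 12 genes and higher in 0 (8 lower over the list alone), among them the pore-forming protein Mpeg1 (-0.46 ± 0.05) and the complement component C1qa (-0.47 ± 0.07), at adjusted p = 1.52e-05 by camera and adjusted p = 0.442 with an estimated correlation. Both genes were dim, near the array medians, with Mpeg1 going from a signal of 32.2 ± 0.7 to 19.2 ± 1.6 and C1qa from 34.8 ± 3.2 to 20.8 ± 2.7. The macrophage and dendritic count was 3 without mouse 145 and 4 without mouse 146, 143 or 144, and the B cell count was 4 without mouse 143. Of 10 B cell and plasma cell markers 2 fell and 0 rose, Igha, the heavy chain of IgA (-2.20 ± 0.32), and the plasma cell regulator Prdm1 (-0.36 ± 0.06) (5 lower when adjusted over the list alone; camera adjusted p = 0.00511; adjusted p = 0.431 with an estimated correlation). Neutrophil and mast cell markers were lower in 4 of 7 genes and higher in 0 (4 lower over the list alone; camera adjusted p = 0.0141; adjusted p = 0.431 with an estimated correlation), and in 1 without mouse 145, 148 or 144 and 2 without mouse 146 or 143. The mast cell proteases Mcpt1 and Mcpt2 had values of -1.38 ± 0.34 and -1.32 ± 0.33 (adjusted p = 0.0289 each). Both calls were lost without mouse 145, 146, 148, 143 or 144, where the adjusted p of Mcpt1 was 0.0838, 0.0869, 0.067, 0.0612 and 0.0945 and that of Mcpt2 0.0802, 0.0889, 0.0694, 0.0608 and 0.0946, and with robust variance moderation (0.128 and 0.126, the highest of ranges from 8.29e-05 and 8.22e-05).

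**Figure D2:**
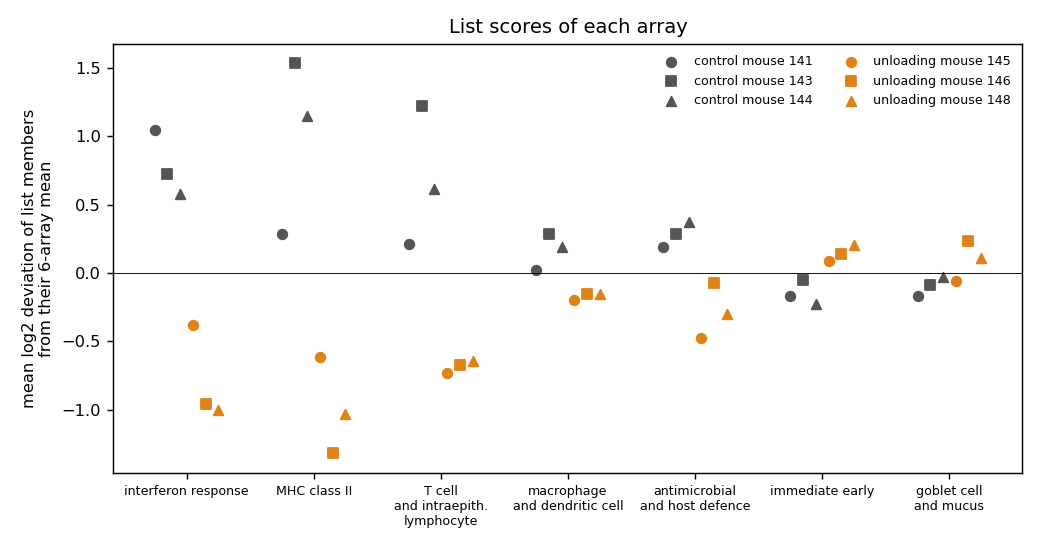
The y axis gives, for each array, the mean log2 deviation of a list's members from their mean over the 6 arrays, with control mice in grey and unloading mice in orange. Control interferon scores lie between 0.58 and 1.04 and unloading scores at or below -0.38, while T cell scores lie between 0.21 and 1.22 in controls and between -0.73 and -0.64 in unloading.

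Antimicrobial and host defence genes were lower in 11 of 22 measured and higher in 0 (14 lower when adjusted over the list alone; camera adjusted p = 1.99e-06; adjusted p = 0.431 with an estimated correlation). Without mouse 148 or 144 the count was 7 or 6. Reg3g, a C-type lectin that kills Gram-positive bacteria, went from 654 ± 218 to 144 ± 110, a change of -2.23 ± 0.42 (limma adjusted p = 0.0109, and 0.0728 with robust variance moderation, the highest of a range from 1.88e-05). The acute-phase apolipoprotein Saa3 fell by 1.00 ± 0.11, from a signal of 134 ± 23.9 to 58.5 ± 3.1. Duoxa2, the maturation factor of the hydrogen peroxide producing oxidase Duox2 (-0.42 ± 0.07), and the peptidoglycan-binding protein Pglyrp1 (-0.41 ± 0.08) fell as well. Of T cell and of macrophage and dendritic cell markers, 15 of 16 and 7 of 12 were lower in the same arrays, and 1 of the list's tested members, Gbp2, is also an interferon response gene. Among 21 cytokine and chemokine genes, 1 was higher and 3 lower over all genes and over the list alone (camera adjusted p = 0.0683), the inflammatory cytokine Il1b (-0.47 ± 0.07) and the monocyte chemokine Ccl8 (-0.58 ± 0.07) among the falls. Both genes were dim, with mean signals of 29.7 in control and 16.8 in unloading for Il1b, and 45.8 and 25.5 for Ccl8. The cytokine list was called lower by camera without mouse 148 (adjusted p = 0.0495) or 141 (0.0282), within 0.0282 to 0.233 with an array left out. Tnf had -0.10 ± 0.05 (adjusted p = 0.237). Il6 and Il10 were under the filter on dim genes, with signals of 3.87 ± 0.76 and 6.88 ± 0.32 in unloading and 3.58 ± 0.30 and 8.75 ± 1.01 in control. Of 25 microbial sensing and NF-kB genes, 1 was higher and 2 lower, over all genes and over the list alone (camera adjusted p = 0.053). The sensing list was called lower without mouse 148 (0.0249) or 141 (0.0282), the highest with an array left out being 0.1; 0 were higher without mouse 145, 146, 148, 141 or 144, and 1 was lower without mouse 145, 148 or 144. Tlr3, a sensor of double-stranded RNA, fell by 0.51 ± 0.08, and Tlr4, the lipopolysaccharide receptor, had -0.13 ± 0.08 (adjusted p = 0.266). Outside the lists, Upp1, a uridine phosphorylase, fell by 2.96 ± 0.26, from a signal of 1793 ± 409 to 225 ± 97.3.

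**Figure D3:**
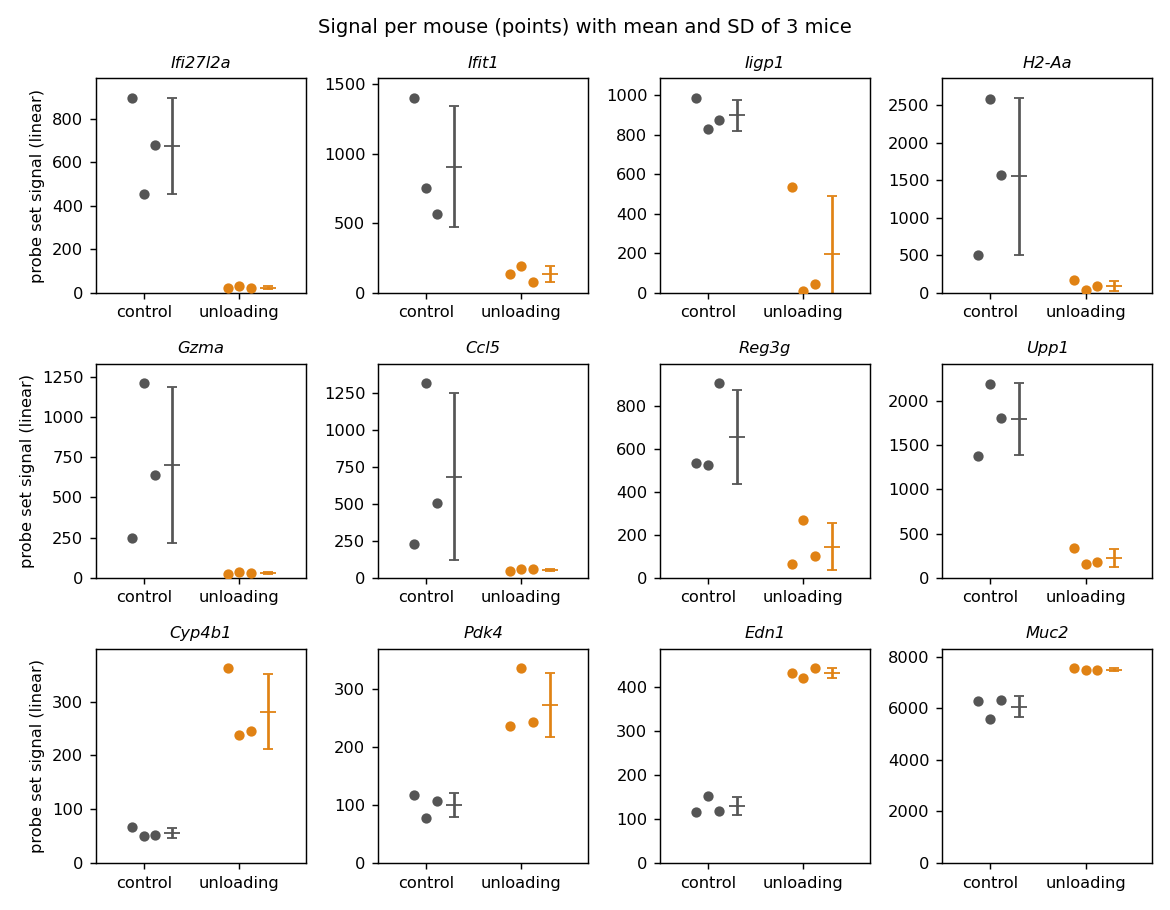
Linear probe set signals of 12 genes are plotted per mouse, with the mean and SD of the 3 mice of each group beside the points. Ifi27l2a, Gzma and Ccl5 stay under 60 in unloading mice, Iigp1 has 1 unloading mouse at 535, and Cyp4b1, Pdk4 and Edn1 are higher in each unloading mouse than in each control.

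The largest rise after that of Cyp4b1 was that of the carboxylesterase Ces1d (1.95 ± 0.28), followed by the secreted matrix protein Ccn3 (1.68 ± 0.13), the vasoconstrictor peptide gene Edn1 (1.63 ± 0.09) and the imprinted long noncoding RNA Meg3 (1.62 ± 0.20). Tppp3, a tubulin-binding protein, rose by 1.42 ± 0.19, Slc35e3 by 1.31 ± 0.09, the inhibitory G protein subunit Gnai1 by 1.24 ± 0.12, Depp1 by 1.17 ± 0.18 and the tetraspanin Tspan33 by 1.09 ± 0.13. Pdk4, the kinase that restrains pyruvate dehydrogenase, rose by 1.31 ± 0.16 from a signal of 100.4 ± 20.9 to 272 ± 55.6. Pck1, the cytosolic enzyme of gluconeogenesis, rose by 1.13 ± 0.07. Some of these sizes depend on the probe set taken, though the calls did not: with the mean of a gene's probe sets, dim ones included, Meg3 had 0.64, Gnai1 0.71, Pck1 0.41 and Tspan33 0.54, and without less specific probe sets Gnai1 had 0.46 and Tspan33 0.22. These 12 rises had limma adjusted p-values between 0.000158, for Edn1, and 0.00505, for Depp1.

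Xenobiotic metabolism genes were higher in 6 and lower in 1 of 31 (6 and 2 over the list alone; camera adjusted p = 0.551), with the sulfotransferases Sult1c2 and Sult1a1 rising by 1.01 ± 0.11 and 0.98 ± 0.15. Without mouse 145 the higher genes were 3, and the lower were 0 without mouse 145, 146, 148 or 141 and 2 without mouse 143. PPAR target and fatty acid oxidation genes were higher in 8 and lower in 1 of 24 (11 and 3 over the list alone; camera adjusted p = 0.0509). Without mouse 145 or 146 the higher genes were 5, without mouse 144 they were 4, and without mouse 148 there were 4 higher and 3 lower. The PPAR list was called higher by camera without mouse 145 (adjusted p = 0.0469), 146 (0.042) or 141 (0.0137), the highest with an array left out being 0.102. Angptl4, an inhibitor of lipoprotein lipase, rose by 0.44 ± 0.07, while the acyl-CoA dehydrogenase Acadl fell by 0.41 ± 0.06. Glucocorticoid target genes were higher in 6 and lower in 2 of 23 (8 and 2 over the list alone; camera adjusted p = 0.0633). It was called higher without mouse 146 (0.0302), 141 (0.0476) or 143 (0.0119), the highest with an array left out being 0.176, and 1 gene was lower without mouse 145, 146, 141, 143 or 144. The transcription factor Klf9 rose by 0.55 ± 0.08, Hsd11b1, which regenerates active glucocorticoid, fell by 0.43 ± 0.07, and Fkbp5 had -0.10 ± 0.08 (adjusted p = 0.436). Circadian clock genes were higher in 3 and lower in 1 of 18 (5 and 1 over the list alone; camera adjusted p = 0.138), with the clock repressor Cry2 rising by 0.50 ± 0.08. The clock list was called higher without mouse 146 (0.0291, up to 0.333 with another array left out); 1 was higher without mouse 145 or 144, and 0 lower without mouse 145, 146, 141 or 143. Lipogenesis genes were higher in 2 and lower in 1 of 18 (2 and 2 over the list alone; camera adjusted p = 0.889), where the glucose-responsive transcription factor Mlxipl rose by 0.73 ± 0.08 and the glycerol-phosphate acyltransferase Gpam by 0.61 ± 0.09. The lipogenesis list had a median of -0.02 and camera pointed lower, whereas fry pointed higher (adjusted p = 0.652). Its lower genes were 0 without mouse 145, 141 or 144 and 2 without mouse 146 or 143.

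Goblet cell and mucus genes were higher in 7 of 24 and lower in 0, with the same counts when adjusted over the list alone and a median of 0.17 that was -0.07 when arrays were scaled on hybridization controls, against -0.18 for all genes. Ern2, an endoplasmic reticulum stress sensor of mucus-secreting cells, rose by 0.76 ± 0.07, and the kallikrein Klk1 by 0.55 ± 0.07. Muc2, the main secreted mucin of the colon, went from 6071 ± 407 to 7502 ± 50.3, a change of 0.31 ± 0.05 (limma adjusted p = 0.00709). On hybridization-control scaling the Muc2 change was 0.06 (adjusted p = 0.654, with a range of 0.00347 to 0.654). The list was called higher by camera (adjusted p = 0.015; adjusted p = 0.481 with an estimated correlation), and the call was lost without unloading mouse 146 (adjusted p = 0.0704). The mean log2 deviation of the list's members was -0.06 in unloading mouse 145, within the control range of -0.17 to -0.03. It was 0.23 in mouse 146 and 0.11 in mouse 148. Mucins and mucin glycosylation enzymes were higher in 6 and lower in 2 of 30 (6 and 4 over the list alone; camera adjusted p = 0.853), with B3gnt6, which builds core 3 O-glycans, rising by 0.99 ± 0.17 and the sialyltransferase St6galnac2 by 0.57 ± 0.07.

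Crypt stem cell and Wnt target genes were higher in 3 of 17 and lower in 0 (4 higher over the list alone; camera adjusted p = 0.103). Sox9, a transcription factor of crypt progenitors, rose by 0.78 ± 0.11, and the stem cell receptor Lgr5 had 0.15 ± 0.09 (adjusted p = 0.275). Deep crypt secretory cell genes were higher in 4 of 10 and lower in 0 (5 higher over the list alone; camera adjusted p = 0.148), and in 1 without mouse 148 or 144 and 2 without mouse 141, with 1 lower without mouse 146. Absorptive colonocyte genes moved both ways, with 4 higher and 7 lower of 24 (4 and 10 over the list alone; camera adjusted p = 0.129) and 2 higher without mouse 146 or 144. Slc51b, a subunit of the basolateral bile acid exporter, fell by 0.97 ± 0.11, while Guca2a, the guanylin precursor, had 0.45 ± 0.05 (limma adjusted p = 0.00177; on hybridization-control scaling 0.20 with an adjusted p of 0.131, the highest of a range from 0.000725). Enteroendocrine genes were higher in 1 of 16 and lower in 0 (0 in either direction over the list alone; camera adjusted p = 0.524). Without mouse 146 they were higher in 4 and called (0.0302, up to 0.905 with another array left out), and without each other mouse higher in 0. Tuft cell genes were lower in 2 of 15 and higher in 0, with the same counts over the list alone (camera adjusted p = 0.0509). The tuft list was called lower without mouse 146 (adjusted p = 0.0358), 148 (0.0495) or 143 (0.0187), the highest with an array left out being 0.132, although its lower genes were then 0, 0 and 1, and 0 without mouse 145 and 1 without mouse 141 or 144. Ion and water transport genes were higher in 6 of 33 and lower in 0 (7 and 1 over the list alone; camera adjusted p = 0.174), with the water channel Aqp1 rising by 1.01 ± 0.14. Without mouse 144 the higher genes were 3, and without mouse 148 there was 1 lower. Notch pathway genes were higher in 2 of 18 and lower in 0 (1 higher over the list alone; camera adjusted p = 0.935). Without mouse 145, 148, 141 or 144 there were 0 higher, without mouse 146 or 143 there was 1, and without mouse 141 there was 1 lower.

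Cell junction and barrier genes split, with 4 higher and 5 lower of 25 (6 and 6 over the list alone; camera adjusted p = 0.979). Higher and lower counts were 1 and 1 without mouse 145, 2 and 1 without mouse 146 or 141, 1 and 2 without mouse 148, and 0 and 1 without mouse 144. Cdh17, an intestinal cadherin, fell by 0.34 ± 0.06. Among the higher genes were the claudins Cldn2 (0.62 ± 0.14), Cldn23 (0.37 ± 0.08) and Cldn4 (0.29 ± 0.07). Their limma adjusted p-values were 0.023, 0.0204 and 0.0217, and their calls were lost in 4, 4 and 5 alternatives. The scaffold protein Tjp1 had -0.09 ± 0.08 (adjusted p = 0.481), Ocln 0.21 ± 0.10 (adjusted p = 0.18) and the adherens junction cadherin Cdh1 -0.09 ± 0.05 (adjusted p = 0.217).

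Immediate early genes, which respond within minutes to stimulation, were higher in 11 of 22 and lower in 0 (13 higher over the list alone; 6 higher over all genes without mouse 148 or 144), with a median of 0.23 that was 0.01 on hybridization-control scaling, against -0.18 for all genes. The AP-1 subunit Fosb rose by 0.75 ± 0.08, from 517 ± 40.5 to 879.6 ± 59.7, and the transcription factor Klf2 by 0.86 ± 0.09. Camera called the list higher (adjusted p = 0.000125; adjusted p = 0.473 with an estimated correlation). Heat shock genes had a median of 0.18, with 0 of 16 passing limma over all genes or over the list alone (camera adjusted p = 0.103). The heat shock list was called higher by camera at its preset correlation without mouse 146 (adjusted p = 0.0042) or 141 (0.00659), with 1 gene passing in each. Its adjusted p reached 0.802 with another array left out, and was 0.761 over all 6 arrays with an estimated correlation. The co-chaperones Ahsa1 (0.25 ± 0.08) and Dnajb1 (0.40 ± 0.12) had limma adjusted p-values of 0.0586 and 0.0599. Unfolded protein response genes were higher in 2 and lower in 2 of 27, also over the list alone (camera adjusted p = 0.935), with the phosphatase subunit Ppp1r15a rising by 0.81 ± 0.06. The list's median was -0.004 and its mean 0.04, while camera pointed lower. Without mouse 145 there were 4 higher and 0 lower, and without mouse 148, 141 or 144 there were 0 lower. Apoptosis and p53 target genes were higher in 4 and lower in 4 of 20, also over the list alone (camera adjusted p = 0.749), with the p53 target Zmat3 rising by 0.49 ± 0.07 and the apoptosis effector Bak1 lower (-0.43 ± 0.07). Without mouse 145, 148 or 144 the higher genes were 2.

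Ribosomal protein genes were higher in 9 of 25 and lower in 0 (14 higher over the list alone). The 9 became 0 without mouse 148, 1 without mouse 146, 141 or 144 and 3 without mouse 145. The genes had a small median change of 0.13, which was -0.12 on hybridization-control scaling, against -0.18 for all genes. Camera called these genes higher (adjusted p = 0.000105; adjusted p = 0.473 with an estimated correlation), and the call was lost on hybridization-control scaling (adjusted p = 0.321).

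Genes of hypoxia and glycolysis were lower in 6 and higher in 1 of 22 (9 and 1 over the list alone; 3 lower over all genes without mouse 144, and 0 higher without mouse 145, 146 or 144). The oxygen sensor Egln3 (-0.82 ± 0.12), the hexokinase Hk2 (-0.53 ± 0.09) and the phosphofructokinase Pfkp (-0.48 ± 0.09) fell. Camera called the hypoxia list lower (adjusted p = 0.0259; adjusted p = 0.473 with an estimated correlation), and the call was lost without control mouse 141 (adjusted p = 0.0615). Oxidative phosphorylation genes were lower in 1 of 31 and higher in 0, also over the list alone (camera adjusted p = 0.0509), the lower gene being cytochrome c, Cycs (-0.28 ± 0.05). Without mouse 143 there were 4 lower and the list was called lower (0.00185, up to 0.186 with another array left out). Cholesterol synthesis genes were lower in 1 of 19 and higher in 0, also over the list alone. That gene, Fdps, which makes farnesyl diphosphate, had -0.45 ± 0.10 (limma adjusted p = 0.0212), lost without mouse 145 (adjusted p = 0.0727), 148 (0.0709) or 144 (0.0746, the highest of a range from 0.000139). The cholesterol list was called lower by camera (adjusted p = 0.036; adjusted p = 0.686 with an estimated correlation), and not without mouse 145 (0.0931), 148 (0.15) or 144 (0.182), where 0 genes were lower, with 1 higher without mouse 148 and 3 lower without mouse 143. Cell cycle genes were lower in 1 of 33 and higher in 0 (0 over the list alone), with 5 lower without mouse 143, 0 lower without each other mouse and 3 higher without mouse 148, and the proliferation marker Mki67 had -0.03 ± 0.10 (adjusted p = 0.882). The cell cycle list was called lower by camera (adjusted p = 0.046; adjusted p = 0.686 with an estimated correlation), and not without mouse 148 (0.676) or 144 (0.158).

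**Figure D4:**
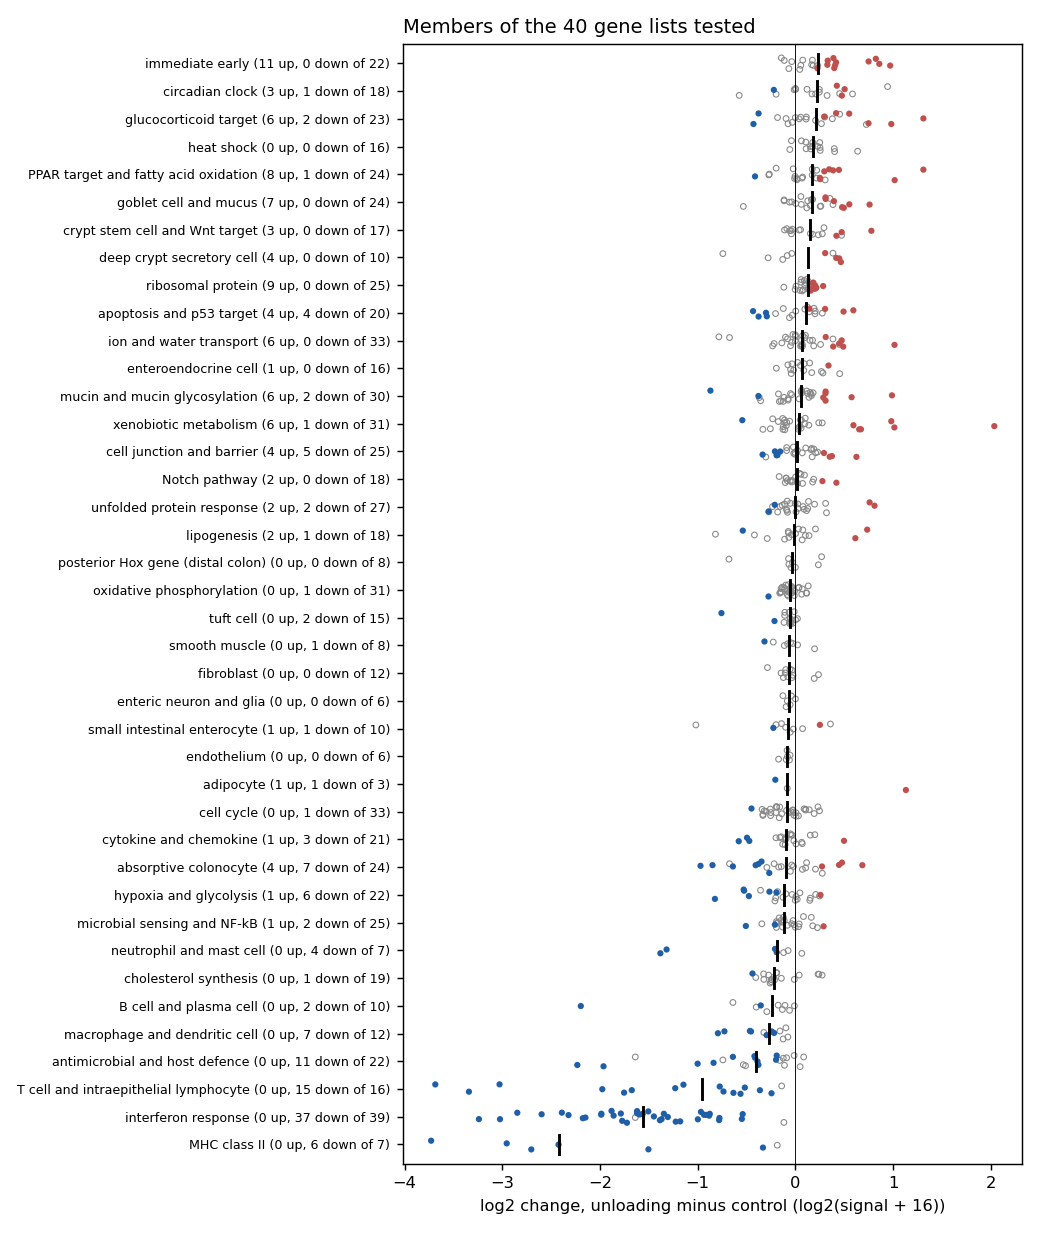
Each line is 1 of the 40 gene lists tested, each circle a measured member at its log2 change, unloading minus control, filled red (higher) or blue (lower) where the limma adjusted p was under 0.05, and the black bar is the list's median. The medians of the MHC class II (-2.42) and interferon response (-1.56) lists lie furthest from 0.

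Markers of connective tissue and other sources were tested in the same way. Over all genes, 0 of 12 fibroblast (camera adjusted p = 0.124), 0 of 6 endothelial (0.0996), 0 of 6 enteric neuron and glia (0.138) and 0 of 8 posterior Hox genes (0.551) passed limma, and 0 passed over each list alone, while 1 fibroblast gene was lower without mouse 143. Their members of smallest p by limma included the fibroblast collagen Col6a2 (-0.29 ± 0.10, limma adjusted p = 0.0766), the endothelial co-receptor Eng (-0.17 ± 0.05, limma adjusted p = 0.0565) and the neuronal receptor kinase Ret (-0.13 ± 0.05, limma adjusted p = 0.0875). Smooth muscle markers were lower in 1 of 8 and higher in 0, also over the list alone (camera adjusted p = 0.138), and in 0 without mouse 145. Small intestinal enterocyte markers were higher in 1 and lower in 1 of 10, also over the list alone (camera adjusted p = 0.366); with an array left out 0 were lower, and 0 higher without mouse 145, 146, 148 or 144. Of 3 adipocyte markers, Pck1 was higher and 1 lower, also over the list alone (camera adjusted p = 0.937), and the list's median of -0.08 and mean of 0.28 differed in sign, and 0 were lower without mouse 145, 146, 148, 141 or 144. The red blood cell list had 1 measured gene and was not tested.

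Measures of array quality were compared by two-sided exact permutation tests, which cannot go below p = 0.1 with 3 arrays against 3. The 3' over 5' signal ratio of Gapdh was 0.859 ± 0.005 in unloading and 0.834 ± 0.026 in control (exact p = 0.3), and that of beta-actin 2.08 ± 0.06 and 1.86 ± 0.07 (exact p = 0.1, the smallest possible). Bacterial hybridization controls averaged a signal of 916 ± 78.8 in unloading and 768 ± 16.5 in control (exact p = 0.1).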

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

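The test of the surplus of higher genes against scaling, and the scaling on hybridization controls, were chosen only after that result was seen.

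The control probe sets, outside the gene comparison, had higher mean signals in unloading. Bacterial hybridization controls, added in equal amounts to each hybridization, had a mean signal 1.19 times as high in unloading as in control over 18 probe sets (836, 994 and 918 against 761, 757 and 787; exact p = 0.1, the smallest that 3 arrays against 3 can give). Poly-A controls, added to the RNA before labelling, were 1.12 times as high over 24 probe sets (71.0 ± 8.0 against 63.1 ± 4.5, SD, n = 3; exact p = 0.3). Among 4396 probe sets past the filter with no gene name or several, 929 were higher and 198 lower in unloading when each probe set was tested by limma.

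More genes were higher (1424) than lower (793), and a candidate explanation is the scaling between arrays. The share of higher genes, 64.2% in the deposited scaling, was 50.7% after quantile normalization and 53.02% after cyclic loess, but both methods draw the arrays' distributions together and with them the share towards a balance, so these values do not decide it. With median centring the share was 69.6%. Scaled on the hybridization controls, 318 genes were higher and 4915 lower, and the median of all genes was -0.18. In the deposited table the trimmed mean was higher in each unloading array (72.3 to 72.9) than in each control (69.4 to 71.3). The array medians lay the other way, at 20.5 to 20.7 in unloading and 20.8 to 21.2 in control. Scaling and an effect of unloading cannot be told apart here, since the amount of RNA per cell was not measured.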

How the results depend on the processing

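The scaling on hybridization controls was chosen after seeing the data. Of the 123 named genes that passed, 64 kept the call in each alternative recomputed for single genes and 59 lost it in at least 1, 13 of them only when an array was left out; scaling on hybridization controls ended 31 of these calls. The cause was not tested unless stated. Signal over background limits the dim genes: the interferon list's median of -1.56 was -1.84 with a pseudocount of 1 and -1.17 with 64. Leaving out an array lowers the number of samples and with it the power. A 3' over 5' ratio within an array does not move with centring, so no centred value is given for it. The tests gave the 13 called lists the same direction in the alternatives for lists that give one, which fry's mixed test does not. Camera's direction is relative to other genes. On hybridization-control scaling the goblet cell and ribosomal medians were negative (-0.07 and -0.12), against -0.18 for all genes. The highest adjusted p of the 13 lists was in each case that with an estimated correlation.

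The count of changed genes (2217; 1424 higher, 793 lower) was 5108 (3593 and 1515) with 1 test per probe set, where more units were tested, 3506 (2161 and 1345) at a threshold of 0.1, 5233 (318 and 4915; 1108 of the calls shared, same sign) on hybridization-control scaling, and 1166 to 2062 (755 to 1340 higher, 411 to 722 lower) with an array left out. The count of called lists (13) was 0 with an estimated correlation and 34 by fry's mixed test, 11 of them shared, and ranged from 11 to 18 with an array left out.

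With an estimated correlation the adjusted p was 0.431 for the interferon, antimicrobial, B cell and neutrophil lists, 0.442 for MHC class II, T cell and macrophage lists, 0.473 for immediate early, ribosomal and hypoxia lists, 0.481 for goblet cells and 0.686 for cell cycle and cholesterol. Adjusted p-values of lists that lost the call were as follows. Cell cycle had 0.141 with no filter, 0.47 by fry, 0.219 by fry's mixed test and 0.00372 to 0.676 with an array left out. Cholesterol synthesis had 0.0598 with no filter, 0.0543 without less specific probe sets, 0.392 by fry, 0.0924 by fry's mixed test and 0.000446 to 0.182 with an array left out. Goblet cell genes had 0.0768 by fry and 0.000321 to 0.0704 with an array left out. Hypoxia and glycolysis had 0.0683 by fry and 0.00722 to 0.0615 with an array left out. Ribosomal protein genes had 0.321 on hybridization-control scaling. Of the 27 lists not called, 9 were called with at least 1 array left out, with lowest adjusted p-values of 0.00185 (oxidative phosphorylation), 0.0042 (heat shock), 0.0119 (glucocorticoid target), 0.0137 (PPAR target), 0.0187 (tuft cell), 0.0249 (microbial sensing), 0.0282 (cytokine), 0.0291 (circadian clock) and 0.0302 (enteroendocrine). On hybridization-control scaling 7 were called: circadian clock 0.000587, glucocorticoid 0.000788, heat shock and PPAR 0.00975 each, oxidative phosphorylation 0.0127, crypt stem cell 0.0152 and deep crypt 0.0215. With no filter these were crypt stem cell, glucocorticoid and heat shock (0.0385 each), cytokine (0.0327) and PPAR (0.0122); with quantile normalization glucocorticoid (0.0425) and PPAR (0.0433); with cyclic loess oxidative phosphorylation (0.028); with the mean of probe sets crypt stem cell (0.0256) and tuft cell (0.0414); without less specific probe sets tuft cell (0.0418) and heat shock (0.0421); by fry adipocyte (0.0303), crypt stem cell (0.0451), and microbial sensing, PPAR and mucin glycosylation (0.0487 each).

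Lists that were not called and changed direction stayed uncalled there. With no filter the adjusted p was 0.303 (adipocyte), 0.668 (unfolded protein response) and 0.805 (lipogenesis); for cell junctions it was 0.988 with median centring and 0.827 with cyclic loess; for Notch it was 0.618 with the mean of probe sets; by fry it was 0.413 (unfolded protein response) and 0.652 (lipogenesis). With an array left out the ranges were 0.78 to 0.999 (adipocyte), 0.28 to 0.986 (unfolded protein response), 0.28 to 0.905 (lipogenesis), 0.762 to 0.986 (cell junction), 0.684 to 0.984 (Notch) and 0.362 to 0.967 (apoptosis).

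Single genes that changed sign were Lrig1 (-0.064) and Rps18 (-0.0401) without less specific probe sets, and Prom1 (-0.0723), Rps18 (-0.0352), Rps15 (-0.0587), Rpl10a (-0.0923), Lgr5 (-0.0347) and Ocln (-0.0233) on hybridization-control scaling, all above that scaling's median of -0.18. Mki67 ranged from -0.0913 to 0.098 with an array left out. Sizes also depend on the probe set: with the mean of a gene's probe sets, which takes in dim ones, Meg3 had 0.64, Gnai1 0.71, Pck1 0.41, Tspan33 0.54, Rtp4 -1.50, Sox9 0.48, Klk1 0.32, Klf9 0.31, Gpam 0.27, St6galnac2 0.30, Pfkp -0.29, Acadl -0.23, Bak1 -0.25 and Fdps -0.23, all still called. With a pseudocount of 64 changes of dim genes shrank and stayed called, as for Cd8a (-0.37), Il1b (-0.21) and Ciita (-0.13).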

Other observations

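The tests of interferon genes against lymphocyte scores and scaling, of MHC class II genes against macrophage and B cell scores, the test of heat shock genes, and the gene families were chosen only after the results they bear on were seen.

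Genes were grouped by the letters that open their symbols, except that the H2 and Ms4a genes were set as families by separate rules. Immune families were among the lower ones. Most of those given here share members with the fixed lists, so they are not separate evidence. The lists hold 3 of the 5 Ifit, 4 of the 6 Gbp, 3 of the 7 Oas, 5 of the 17 H2, 2 of the 10 Psmb and 0 of the 7 Gimap genes. Of 420 families with at least 5 tested genes, camera called 17 at its preset correlation, and each of the 17 had an adjusted p = 0.894 with an estimated correlation. All 5 Ifit genes, 6 of 7 Gimap genes (GTPases of lymphocyte survival), 5 of 7 Oas genes (sensors of double-stranded RNA) and 4 of 6 Gbp genes (interferon-induced GTPases) were lower, and 0 higher. Among 10 Psmb genes, which encode beta subunits of the proteasome, 6 were lower, and the immunoproteasome subunits Psmb8 (-1.99), Psmb9 (-1.56) and Psmb10 (-0.65) were lowest. Of 17 H2 genes 11 were lower, including the class I heavy chains H2-D1 (-0.79) and H2-K1 (-0.69), and H2-Ke6, which encodes a metabolic enzyme, was higher (0.35). These members were chosen after their values were seen.

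Some families leaned higher. Of 13 Snhg genes, hosts of small nucleolar RNAs, 6 were higher and Snhg10 (-0.24, chosen after its value was seen) was lower. Of 244 Zfp zinc finger genes 42 were higher and 5 lower, and of 21 Mettl methyltransferase-like genes 7 were higher and 0 lower. The ribosomal families Rpl (7 of 22) and Rps (9 of 27) had 0 lower. Their medians, 0.23 for Snhg, 0.07 for Zfp, 0.11 for Mettl, 0.09 for Rpl and 0.12 for Rps, were 0.01, -0.12, -0.07, -0.15 and -0.11 on hybridization-control scaling, where all but that of Snhg turned negative because that scaling moves the median of all genes to -0.18. Relative to that median they lay at 0.20, 0.07, 0.11, 0.03 and 0.07. The fixed list of ribosomal genes holds 11 of the Rpl and 12 of the Rps genes.

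The fall of interferon and MHC class II genes was weighed against scaling and against fewer immune cells in the unloading preparations. The 4 scalings tried put the median of all genes between -0.18 and 0.02, and the interferon median was -1.55 at its highest over them. Shifts of that size could not have removed the interferon fall. The values therefore argue only against scaling differences of that size as its whole cause. Lymphocytes are a candidate source, since no sort removed them and Gzma, Ccl5 and Gzmb fell from signals of 699, 684 and 427 to 30.6, 52.3 and 25.0, and none of the 16 measured T cell genes is in another list. Within groups, T cell scores correlated with interferon scores at r = -0.40 (one-sided exact p = 0.194 over 36 pairings) and with MHC class II scores at r = 0.79 (p = 0.139). Each one-sided p of these correlations was taken on the side to which the observed r pointed. MHC class II scores correlated at r = 0.77 (one-sided exact p = 0.139) with macrophage and dendritic cell scores and at r = 0.72 (p = 0.111) with B cell and plasma cell scores, so fewer immune cells and an effect of unloading on the epithelium, which can itself express both gene sets, cannot be told apart with 6 arrays. The labels give no cage, array batch or scan date. A difference between the groups in cage or processing, apart from unloading, therefore cannot be told apart from these either.

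The rise of immediate early genes was weighed against scaling and against warmth or handling during isolation. Camera still called the list higher at an adjusted p of 0.000127 or less after quantile normalization and cyclic loess. Since camera compares a list with other genes, a shift shared by all genes of an array largely cancels. These calls therefore show a rise relative to other genes and do not decide on scaling. The list's median was 0.01 on hybridization-control scaling, against -0.18 for all genes. Handling could raise heat shock genes too, and these had a camera adjusted p of 0.103 (0.761 with an estimated correlation), with a median of 0.18 and 0 of 16 passing limma. On hybridization-control scaling that median was -0.06, against -0.18 for all genes. Camera called these genes higher with no filter (adjusted p = 0.0385), without less specific probe sets (0.0421) and on hybridization-control scaling (0.00975). With an array left out their adjusted p ran from 0.0042 (without mouse 146) and 0.00659 (without mouse 141), where the list was called higher with 1 gene passing, to 0.802. Handling and an effect of unloading cannot be told apart here, since the labels give no order or time of isolation and the beta-actin 3' over 5' ratio, a measure of RNA quality, was higher in each unloading array (2.06, 2.14 and 2.02) than in each control (1.94, 1.82 and 1.81; exact p = 0.1, the smallest possible), while that of Gapdh had an exact p of 0.3.

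Other splits of the 6 arrays into 3 and 3 number 10 with the real one, too few for a share under 0.05. The real split gave 2217 changed genes and the highest other split 0, so 1 of 10 splits reached the real count. The real split gave 13 called lists and the highest other 17, so 3 of 10 splits reached the real count. Each other split put unloading and control arrays together on each side. The difference between the groups then added to the spread within each side, which lowers the count of changed genes. Part of that difference also stayed between the sides and can add to the called lists. The counts of the other splits are therefore not chance levels, and no conclusion is drawn from them.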
